A study of Homo sapiens with 4 samples.

How the data were processed

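Total RNA was extracted from 786-O cells with TRIzol, and libraries of polyadenylated RNA were prepared from it, per the labels' protocols. The Cas9-expressing parent was a clone made with a lentivirus, and knockout clones were made by infecting it with viruses expressing guides against DEK followed by single-cell sorting, per the labels' protocols. Each of the 4 libraries was assigned to control or DEK knockout, with its replicate number, from its title.

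The authors deposited a single table of TPM, transcripts per 1000000, with 59409 gene symbols and 1 column per library. Each column sums to 1000000, so the values are relative to the other genes of the same library. The submitters' processing notes name cutadapt 1.18, STAR 2.7.8a, featureCounts 2.0.1, DESeq2 1.36.0 and the build hg38, without saying which step each was used for. The gene annotation, the gene lengths and the use of strand are not given in the sources used here.

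Symbols were matched to GENCODE release 29 on GRCh38 for position, gene type, exon length and the GC content of the longest transcript, 54330 by name and 2184 through a table of current symbols. Coordinates are those of that release, counted from 1. Because a TPM value is a read count divided by a length and a library factor, values of genes with few reads fall on steps. The ratio of steps between libraries gave relative depth, and the release's exon lengths gave an estimate of read numbers. Of estimated values under 200 reads, 54.9% were whole to within 0.02, where 4% would be by chance. The remaining genes differ in length between annotations, so the depths of 35.8 to 40.1 (in units of 1000000 reads) are approximate, and read numbers are given only for genes whose values came out whole. Counting intervals and limits cover counting error only. The genes of the mitochondrial genome held 17.2% and 19.0% of TPM in the controls and 16.4% and 16.5% in the knockouts. Differences between replicate libraries exceeded sampling noise, with a chi-square per gene of 1.70 between the controls and 2.89 between the knockouts, which library preparation alone can cause. The chi-square thus does not show whether the libraries of a group are separate cultures. Between the knockouts whole chromosomes differed: with the GC trend removed, the range of chromosome medians was 0.387, against 0.0225 between the controls. This argues against the 2 knockout libraries being preparations of the same cells. For the controls the question stays open. Each library was entered in the fit as a library of its own.

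Genes with at least 1 TPM in at least 2 libraries were kept (15815), and log2(TPM + 1) was fitted with limma 3.58.1 in R 4.3.3 with the group as the only term and a variance prior that follows mean expression. The p-values were adjusted with the Benjamini-Hochberg method at 0.05. Fold changes in log2 are on the log2(TPM + 1) scale, which understates changes of low genes, and fold values without log2 are ratios of mean TPM. With 2 libraries per group an exact permutation test cannot go below p = 0.333, so none was used for single genes. Gene lists were tested with camera with an inter-gene correlation of 0.01, and with an estimated correlation and fry beside it.

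The tests of genes and gene lists, the lists, the rule for the genes named and all alternatives except those given below as added were fixed before the data were examined. The genes named are DEK, the 10 largest rises and the 10 largest falls among genes past the threshold with both knockouts on the same side of both controls and a mean of at least 5 TPM in the higher group, and up to 4 members with the smallest p of each list. Members named to complete a count of 5 or fewer (PFKFB3, PGAM1, ENO1, PFKL, ITGB8, LAMA3, KRT7, CRB3, CCN2, ANKRD1, FJX1, XPC, HMOX1, TKT and ANP32E), the tested markers of lists with fewer than 3 tested members, and the genes opening the closing observations were chosen after their values were seen. Many named genes overlap another annotated gene, for example HOXA9 with HOXA10, TYMS with ENOSF1, CBX3 with HNRNPA2B1 and INHBA with INHBA-AS1, and their values are uncertain to that extent. Some genes that the rule or a count would name are withheld and are not reported here.

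On data simulated for this comparison over 15815 genes, the procedure recovered 50% of genes changed 2-fold and 90% of genes changed 4-fold, and 6.67% of its calls were unchanged genes. The simulation called 150 genes, against 2804 in the data. It changed only genes above a low level, with independent noise and without a GC trend or shifted chromosomes. These rates therefore need not hold for the data. Alternatives covered the pseudocount, the filter, scaling by the median ratio, quantile normalization, the variance prior, a replicate block, a stricter threshold and leaving out each library. Removal of the GC trend with lowess and leaving out chromosomes 1, 7 and 22 were added after the data had been seen. Chromosomes 1 and 7 had the lowest and the highest median difference between the knockouts, and chromosome 22 the highest median log2 fold change between groups. The comparisons along the genome, and a choice of lists in single libraries by the Mann-Whitney test for the closing observations, were added then too. Positions were compared as medians of windows of 40 tested genes, with intervals from 2000 bootstrap draws over genes and 100000 permutations of gene labels for the HOXA cluster (Python 3.11.15, numpy 2.4.6, scipy 1.17.1). A count-based test was not run, since the table holds TPM.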

Results

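Polyadenylated RNA was sequenced from 786-O cells, a human clear cell renal carcinoma line that lacks a functional VHL protein. The comparison asked how the transcriptome differs when DEK, a chromatin-associated protein with histone chaperone activity, is knocked out with Cas9. There were 2 control libraries, labelled as negative control, and 2 libraries from DEK knockout cells, which were derived by single-cell sorting from a Cas9-expressing clone. The labels do not say which clone each knockout library came from, or whether libraries of a group came from separate cultures. The p-values therefore measure only the spread between these libraries, which may be technical for the controls. With the GC trend removed, chromosome medians differed over a range of 0.387 between the knockouts, against 0.0225 between the controls. This argues against a purely technical spread between the knockouts. The values were TPM for 59409 gene symbols. Depth, estimated from the smallest steps of the TPM values, was 38.9 and 39.5 in control 1 and control 2, and 35.8 and 40.1 in knockout 1 and knockout 2, in units of 1000000 reads. On the log2(TPM + 1) scale, Pearson's r across 15815 tested genes was 0.989 between the controls, 0.980 between the knockouts and 0.941 to 0.964 between groups. These correlations are across genes, which are not independent replicates.

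The targeted gene was examined first. DEK lies on chromosome 6 from 18223868 to 18264823 on the minus strand (GRCh38). Its mRNA was at 95.02 and 76.3 TPM in the controls and at 31.4 and 15.7 TPM in the knockouts. The mean fell from 85.6 ± 13.3 to 23.6 ± 11.1 TPM (SD, n = 2 per group), a 3.64-fold lower level, with a log2 fold change of -1.89 (SE 0.33, limma adjusted p = 0.030). The mRNA was thus lower in both knockout libraries but remained detectable, and the values carry no information on the protein. Without control 1 the log2 fold change was -1.73 (adjusted p = 0.14) and without control 2 it was -2.05 (adjusted p = 0.10). Over all alternatives run, its adjusted p lay between 0.0015 and 0.14.

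Knockout and control cells differed over a large part of the transcriptome. Of 15815 tested genes, 1433 rose and 1371 fell in the knockout (limma, Benjamini-Hochberg adjusted p under 0.05). Among changes of at least 2-fold, rises outnumbered falls, with 642 genes against 307, and among changes of at least 4-fold there were 142 against 30. The count depended on single libraries. It was 47 without control 1, 51 without control 2, 5510 without knockout 1 and 3092 without knockout 2. Which direction led depended on them too. Without knockout 1 falls led, with 2375 of the 5510 genes rising, and they led at 2-fold or more as well, with 653 of 1384 rising.

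**Figure D1:**
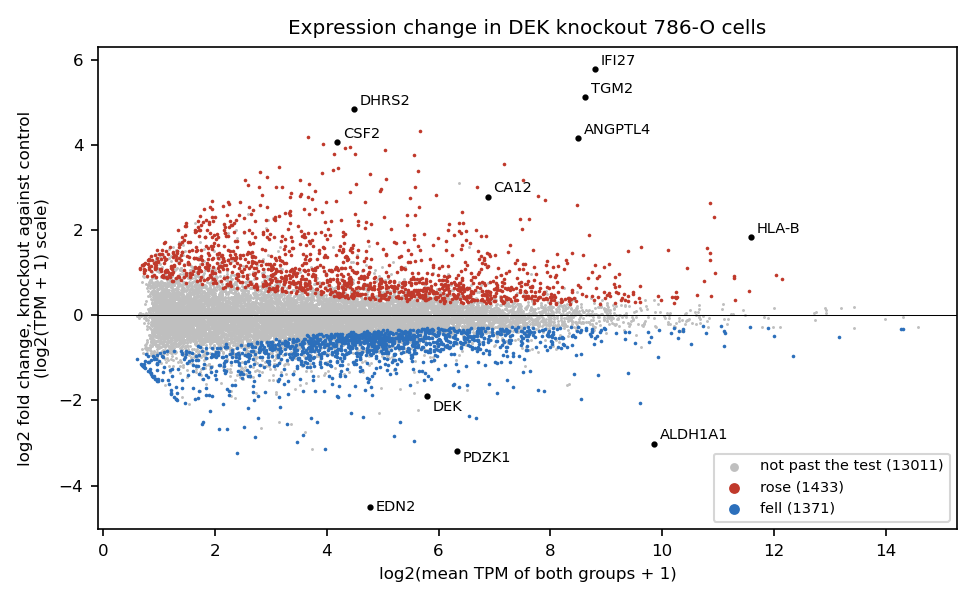
Log2 fold change of each tested gene in DEK knockout against control (vertical axis, log2(TPM + 1) scale) against log2 of its mean TPM plus 1 (horizontal axis), with 2 libraries per group. Red points are the 1433 genes that rose, with IFI27 highest, blue points the 1371 that fell, with EDN2 lowest, and grey points did not pass the test.

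The genes with the largest rises included an interferon-induced gene, secreted factors and 2 neighbouring noncoding RNAs. IFI27, an interferon-induced gene on chromosome 14 (94104836 to 94116698), rose from 14.5 ± 2.53 to 869 ± 264 TPM (SD, n = 2), a 60.1-fold difference with a log2 fold change of 5.79 (SE 0.24, adjusted p = 0.0056). TGM2, which encodes tissue transglutaminase (chromosome 20, 38127387 to 38166578), rose 37.3-fold to 763 ± 224 TPM. ANGPTL4, a secreted regulator of lipoprotein lipase and a HIF target (chromosome 19, 8363289 to 8374373), rose 19.0-fold to 682 ± 219 TPM. DHRS2, a short-chain dehydrogenase, rose from 0.516 to 42.3 TPM, with nearly equal levels in both knockouts. CSF2, encoding the cytokine GM-CSF, rose 38.9-fold, INHBA, the activin A subunit, 25.6-fold, and the secretory granule protein gene SCG5 28.6-fold. SIGLEC15 rose 35.6-fold. The knockout values of some of these genes were far apart, and with either knockout left out the rise was 21.4-fold or 56.5-fold for CSF2, 15.1-fold or 42.1-fold for SCG5 and 12.5-fold or 58.7-fold for SIGLEC15. The noncoding RNA AC078923.1 rose from 0.246 to 23.1 TPM and AC078820.1 from 0.773 to 27.6 TPM. With single libraries left out, the rise was 60.4-fold to 127-fold for AC078923.1 and 19.6-fold to 207-fold for AC078820.1. These 2 genes overlap on the minus strand of chromosome 12, so their reads cannot be fully separated.

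The largest falls included genes of peptide signalling and of retinoid, glyoxylate and transport functions. EDN2, encoding endothelin 2 (chromosome 1, 41478775 to 41484673), fell from 51.5 ± 0.501 to 1.37 ± 0.742 TPM (SD, n = 2), a 37.6-fold difference with a log2 fold change of -4.51 (SE 0.24, adjusted p = 0.0067). ALDH1A1, a retinaldehyde dehydrogenase (chromosome 9, 72900662 to 73080442), fell from 1637 ± 38.4 to 211 ± 89.3 TPM, 7.75-fold. PDZK1, a scaffold of apical membrane transporters, fell 8.69-fold from 143 TPM, and HOGA1, a mitochondrial enzyme of hydroxyproline breakdown, fell 7.97-fold from 82.4 TPM. GFRA1, a coreceptor for GDNF, fell 7.33-fold. ELF3, an epithelial ETS factor, fell 10.3-fold. Some of these falls were uneven between the knockouts. Without knockout 2 they were 27.2-fold for EDN2, 5.96-fold for PDZK1, 5.24-fold for GFRA1 and 6.16-fold for ELF3, and without knockout 1 they were larger, up to 61.1-fold for EDN2 and 32.2-fold for ELF3. Short noncoding RNAs were also among the largest falls. The libraries were of polyadenylated RNA, so these values need not follow the levels of such RNAs in the cells. Of 159 tested snoRNA genes 25 fell and 5 rose, and of 213 miRNA genes 20 fell and 7 rose. Of 61 snRNA genes 6 fell and 5 rose. RMRP, the RNA of RNase MRP, fell 12.5-fold from 18.7 TPM. RNU1-70P, a U1 pseudogene, had an estimated 11 and 18 reads in the controls and 0 in both knockouts, which makes it at least 4.59-fold lower when the limit is set at 3 reads per library. MIR8085 had 14 control reads and 1 knockout read, a ratio of 13.4 (exact 95% interval 2.04 to 566, for counting error only). It lies within BCL3 on the same strand, so these reads may be those of BCL3.

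**Figure D2:**
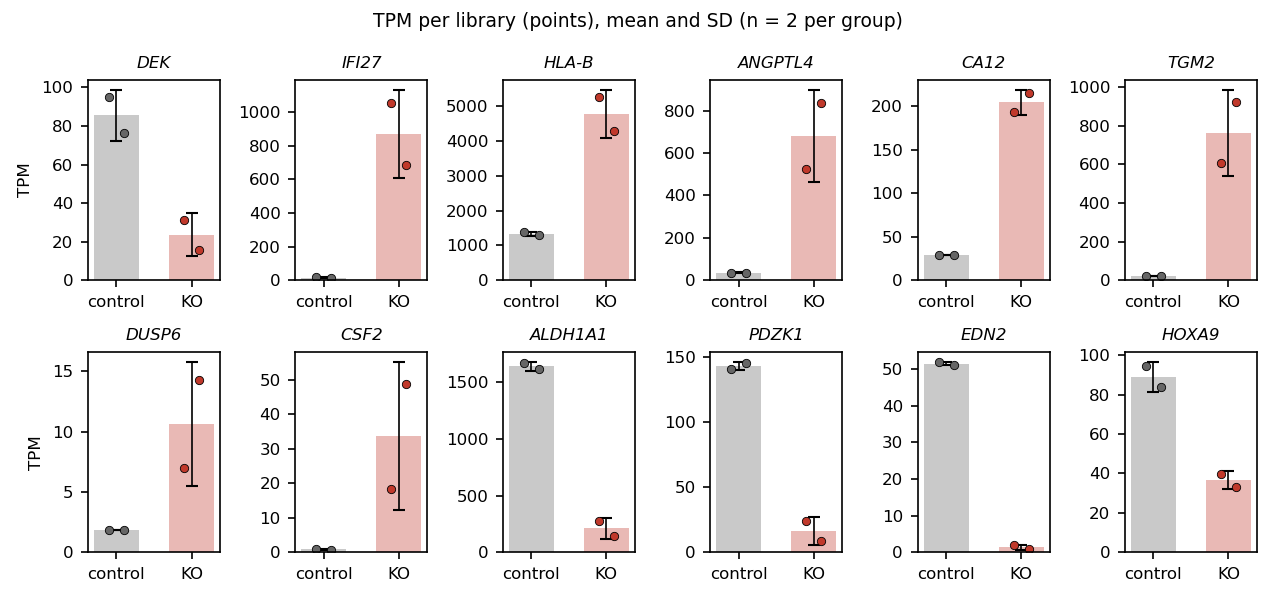
TPM of 12 genes in each library (points) with the group mean (bar) and SD (error bar), n = 2 per group, each panel on its own linear axis from 0. DEK, ALDH1A1, PDZK1, EDN2 and HOXA9 were lower, and the other 7 genes higher, in both knockout libraries than in both controls.

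Of 30 fixed gene lists, 27 had at least 3 tested members. By camera with a preset inter-gene correlation of 0.01, 18 lists were shifted at an adjusted p under 0.05, 9 upwards and 9 downwards. With a correlation estimated for each list, 0 lists passed in camera, the smallest adjusted p was 0.38, and 2 lists had an unadjusted p under 0.05. In that setting camera uses the residual degrees of freedom, few with 2 libraries per group, so a list could hardly pass. The preset setting takes them from the number of genes. The estimate was -0.042 for the HIF, -0.029 for the mesenchymal and 0.0092 for the integrin list, below the preset value. In others it was higher, up to 0.91 for the immediate early list. Failing there thus does not by itself show correlated members. The fry test asks whether the members of a list move on balance in the same direction, whatever the other genes do. Camera compares the members with the other tested genes, so the 2 tests answer different questions. By fry, 15 of the 27 lists passed, 12 of them among the 18. Those of the 18 that did not were the interferon, immediate early, unfolded protein, mitosis, NRF2 and DNA repair lists. The epithelial, HOX and oxidative phosphorylation lists passed fry (adjusted p = 0.027, 0.047 and 0.039) but not camera.

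**Figure D3:**
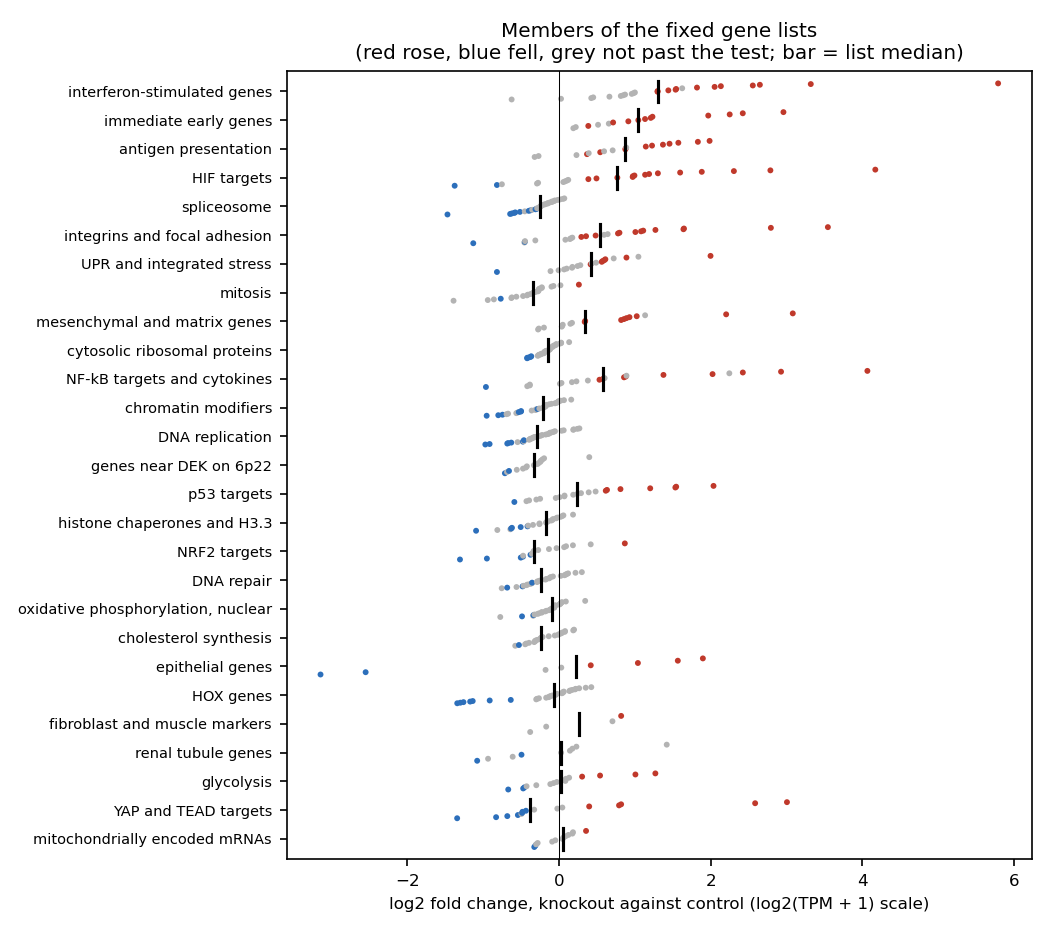
Log2 fold change of each tested member (points) of the 27 fixed gene lists, ordered from the smallest camera p at the top. Red members rose, blue members fell, grey members did not pass the test, and the black bar is the list median, which is 1.30 for the interferon-stimulated genes and -0.25 for the spliceosome.

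Interferon-stimulated genes and genes of antigen presentation were higher in the knockout. Of 24 tested interferon-stimulated genes, 12 rose and 0 fell, with a median log2 fold change of 1.30 (camera adjusted p = 4.7e-09, and adjusted p = 0.38 with an estimated correlation). Adjusted over the list alone, 20 rose. Beside IFI27, IFI6 rose from 501 ± 91.8 to 3199 ± 1006 TPM (SD, n = 2). BST2, which encodes the antiviral protein tetherin, rose 2.46-fold to 2615 ± 21.1 TPM, and MX2, an antiviral GTPase, rose 6.33-fold. In the antigen presentation list 11 of 18 members rose and 0 fell, with a median of 0.88 (camera adjusted p = 2.2e-07, adjusted p = 0.38 with an estimated correlation). Adjusted over the list alone, 15 rose and 2 fell. The class I heavy chain genes, at 6p21, led this list. HLA-B rose from 1340 ± 57.0 to 4789 ± 692 TPM, HLA-C 2.75-fold and HLA-F 4.06-fold, and reads of these similar genes can be misassigned among one another.

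Targets of the hypoxia-inducible factors were mostly higher. In 786-O cells HIF activity does not need hypoxia, because a functional VHL protein is lacking. The list does not separate targets by factor. Of 23 tested targets 14 rose and 2 fell, in counts that were the same when adjusted over the list alone. The median was 0.77 (camera adjusted p = 1.0e-05, adjusted p = 0.38 with an estimated correlation), and it was 0.49 with no filter on low values. CA12, a carbonic anhydrase, rose from 28.7 ± 0.353 to 204 ± 14.8 TPM (SD, n = 2). TGFA, an EGF receptor ligand, rose 3.70-fold to 651 ± 15.8 TPM, and DDIT4, an inhibitor of mTORC1, rose by a log2 fold change of 0.99. The members that fell were VLDLR (log2 fold change -0.82) and PFKFB3 (-1.38). Glycolysis genes went both ways, with 4 of 16 rising and 3 falling and a median of 0.03 (camera adjusted p = 0.59). HK2 rose 2.54-fold, ENO2 2.03-fold, HK1 1.46-fold and PFKP by a log2 fold change of 0.30, while PGAM1 (log2 fold change -0.67), ENO1 (-0.47) and PFKL (-0.46) fell. Adjusted over the list alone, 4 rose and 5 fell.

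Immediate early genes and their feedback regulators were also higher. Of 15 tested members 11 rose and 0 fell, with a median log2 fold change of 1.04 (camera adjusted p = 1.4e-07, adjusted p = 0.38 with an estimated correlation), and 12 rose adjusted over the list alone. DUSP1, a MAP kinase phosphatase, rose 1.89-fold to 334 ± 24.8 TPM (SD, n = 2). PHLDA1 rose 5.68-fold, FOSL1, an AP-1 subunit, 2.37-fold, and SPRY4, an inhibitor of receptor tyrosine kinase signalling, from 0.225 to 4.95 TPM. In the list of NF-kB targets and cytokines 9 of 21 members rose and 1 fell, with a median of 0.58 (camera adjusted p = 3.7e-04, adjusted p = 0.38 with an estimated correlation). Adjusted over the list alone, 11 rose and 3 fell. Beside CSF2, VCAM1, an adhesion molecule, rose 4.31-fold and CSF1, the macrophage growth factor, 1.82-fold, while TNFAIP2 fell 1.96-fold. The median was 0.33 without knockout 2. This list did not pass once genes on chromosomes 1, 7 and 22 were left out (median 0.30, adjusted p = 0.063).

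Adhesion and matrix genes were shifted upwards. Among 24 integrin and focal adhesion genes 13 rose and 2 fell, with a median of 0.54 (camera adjusted p = 1.5e-05, adjusted p = 0.38 with an estimated correlation), and 15 rose and 4 fell adjusted over the list alone. The 2 that fell were ITGB8 (log2 fold change -1.13) and LAMA3 (-0.45). ITGB3 rose from 28.1 ± 0.170 to 90.1 ± 3.58 TPM (SD, n = 2), ITGB5 2.12-fold, ITGA5 2.43-fold and the hyaluronan receptor CD44 7.34-fold. Among 18 mesenchymal and matrix genes 9 rose and 0 fell, with a median of 0.34 (camera adjusted p = 3.1e-04, adjusted p = 0.38 with an estimated correlation), and 10 rose adjusted over the list alone. FN1, fibronectin, rose 1.81-fold to 5833 ± 415 TPM, TGFBI 1.91-fold, MMP14 2.06-fold and SNAI2, a transcription factor of epithelial-mesenchymal transition, 5.60-fold. The epithelial list was not shifted by camera (adjusted p = 0.19) and passed fry (adjusted p = 0.027), and its median (0.22) and mean (-0.12) differed in sign. Of its 8 tested genes 4 rose, CLDN4 (3.81-fold), CLDN1 (3.25-fold), KRT18 (1.34-fold) and KRT7 (log2 fold change 1.04), and 2 fell, ELF3 and CRB3 (-2.55, with uneven knockout values), in counts that were the same adjusted over the list alone. In the list of YAP and TEAD targets 5 of 16 rose and 7 fell (camera adjusted p = 0.59), and 5 rose and 9 fell adjusted over the list alone. F3, tissue factor, rose 6.05-fold and NT5E 9.18-fold, and CCN2 (log2 fold change 0.82), ANKRD1 (0.79) and FJX1 (0.40) also rose, while AJUBA fell 1.40-fold and CRIM1 1.46-fold. That list also had a median (-0.38) and mean (0.12) of opposite sign.

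Stress-related lists were shifted in different directions. Of 21 p53 targets 7 rose and 1 fell, also adjusted over the list alone, with a median of 0.24 (camera adjusted p = 0.0033, adjusted p = 0.38 with an estimated correlation). CDKN1A, the inhibitor of cyclin-dependent kinases p21, rose from 319 ± 6.28 to 736 ± 5.09 TPM (SD, n = 2), GDF15 rose 4.15-fold, PMAIP1 2.95-fold and PLK3 3.23-fold, while XPC fell (log2 fold change -0.59). In the list of the unfolded protein and integrated stress response 7 of 20 rose and 1 fell, with a median of 0.42 (camera adjusted p = 7.1e-05, adjusted p = 0.38 with an estimated correlation), and 12 rose and 1 fell adjusted over the list alone. The member that fell was VLDLR. The chaperone CALR rose 1.49-fold, CRELD2 1.54-fold and TRIB3 1.49-fold. NRF2 targets were shifted downwards, with 1 of 18 rising and 5 falling, also adjusted over the list alone, and a median of -0.34 (camera adjusted p = 0.036, adjusted p = 0.38 with an estimated correlation). FTL, ferritin light chain, fell from 6798 ± 189 to 3513 ± 99.2 TPM, AKR1C3 fell 2.46-fold, NQO1 1.42-fold and ME1 1.40-fold, and TKT fell by 0.38 on the log2 scale. The member that rose was HMOX1 (log2 fold change 0.87). Without knockout 1 the NRF2 list did not pass (median -0.16, adjusted p = 0.27).

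Lists of proliferation, chromatin and RNA processing genes were shifted downwards. Of 35 DNA replication genes 7 fell and 0 rose, with a median of -0.29 (camera adjusted p = 5.5e-04, adjusted p = 0.38 with an estimated correlation), and 15 fell adjusted over the list alone. MCM6, a helicase subunit, fell from 136 ± 2.93 to 84.3 ± 8.28 TPM (SD, n = 2), TYMS 1.59-fold and UHRF1 1.56-fold. Among 25 mitosis genes CCNA2 fell 1.72-fold and UBE2C rose 1.20-fold. The other 23 did not pass the test, with a list median of -0.34 (camera adjusted p = 2.3e-04, adjusted p = 0.51 with an estimated correlation), and 13 fell and 1 rose adjusted over the list alone. Of 32 spliceosome genes 10 fell and 0 rose, with a median of -0.25 (camera adjusted p = 1.5e-05, adjusted p = 0.38 with an estimated correlation), and 17 fell adjusted over the list alone. SRSF2 fell 1.51-fold, HNRNPU 1.56-fold, HNRNPC 1.43-fold and HNRNPA1 1.32-fold. Of 34 cytosolic ribosomal protein genes 5 fell, also adjusted over the list alone, with a median of -0.14 (camera adjusted p = 3.1e-04, adjusted p = 0.38 with an estimated correlation). RPLP0 fell 1.34-fold, RPL7 1.32-fold, RPL5 1.30-fold and RPL3 1.29-fold.

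Of 32 chromatin modifier genes 7 fell and 0 rose, with a median of -0.21 (camera adjusted p = 4.8e-04, adjusted p = 0.38 with an estimated correlation), and 10 fell adjusted over the list alone. CBX3 and CBX5, which encode heterochromatin proteins, fell 1.94-fold and 1.69-fold. PBRM1, a SWI/SNF subunit, fell 1.87-fold and HDAC2 1.43-fold. Of 23 genes for histone chaperones and histone H3.3 5 fell and 0 rose, also adjusted over the list alone, with a median of -0.17 (camera adjusted p = 0.0086, adjusted p = 0.38 with an estimated correlation). NPM1 fell from 656 ± 22.8 to 491 ± 1.03 TPM (SD, n = 2), SET 1.42-fold, NAP1L1 1.54-fold and H3-3A 1.55-fold, and ANP32E fell by 1.09 on the log2 scale. Of 27 DNA repair genes 3 fell, PRKDC 1.28-fold, XRCC5 1.39-fold and PARP1 1.59-fold, with a median of -0.24, and 0 passed adjusted over the list alone. The call of the DNA repair list (camera adjusted p = 0.049, adjusted p = 0.65 with an estimated correlation) was lost without control 2 (adjusted p = 0.053, median -0.22) and without knockout 2 (adjusted p = 0.34, median -0.15).

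The differences between groups followed the GC content of the transcripts. Across 15611 genes, Spearman's rho between log2 fold change and GC content was 0.35, and genes are not independent replicates. The median log2 fold change was -0.33 in the fifth of genes with the lowest GC content, up to 41.2%, and 0.11 in the fifth with the highest, from 57.9%. The rho was 0.28 for knockout 1 and 0.37 for knockout 2 against the controls, 0.27 between the knockouts and 0.13 between the controls. Of the lists shifted downwards, the mitosis and DNA repair lists had the lowest median GC content, at 43.2% and 43.4%. With the GC trend removed from each library, 2790 genes changed, of which 1262 rose and 1528 fell, and 2172 of these also changed without the removal. The DNA repair list was then no longer shifted (median -0.04, adjusted p = 0.33), and the other 17 of the 18 lists kept their call and direction. The oxidative phosphorylation, cholesterol and HOX lists were then shifted downwards as well (camera adjusted p = 0.012, 0.039 and 0.015). All these calls used the preset correlation of 0.01, and an estimated correlation was not run with the GC trend removed. Without the removal, the estimated correlation gave these 3 lists camera adjusted p = 0.38, 0.51 and 0.55.

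Other lists were not shifted by camera, and of these oxidative phosphorylation passed fry. Among 27 nuclear oxidative phosphorylation genes 2 fell, SDHC 1.40-fold and ATP5F1C 1.27-fold (camera adjusted p = 0.059), and 0 passed adjusted over the list alone. Of 13 mitochondrially encoded mRNAs MT-CO3 and MT-ATP6 fell 1.25-fold and 1.24-fold and MT-ND6 rose 1.28-fold (camera adjusted p = 0.85, with a median of 0.05 and a mean of -0.03). For this list and for the cholesterol and renal tubule lists the counts were the same adjusted over the list alone. Of 23 cholesterol synthesis genes INSIG1 fell 1.46-fold and 0 rose (camera adjusted p = 0.078). Of 9 tested renal tubule genes PAX2, a kidney transcription factor, fell 2.20-fold and CDH6 1.41-fold (camera adjusted p = 0.54, with a median of 0.03 and a mean of -0.13). Among markers of other cell types, ACTA2 rose 1.91-fold to 10.4 TPM and was the only 1 of 4 tested fibroblast and smooth muscle markers to change (camera adjusted p = 0.39), and 2 rose adjusted over the list alone. Lists with fewer than 3 tested members were not tested as lists. Of 16 leukocyte markers 2 were tested and neither passed, namely LCP1 (adjusted p = 0.15) and CORO1A (adjusted p = 0.18). Of 13 endothelial markers EGFL7 alone was tested and rose (log2 fold change 0.95), and of 26 cancer-testis antigens PRAME alone was tested and rose (0.87).

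The HOX genes that fell were in a single cluster, and the clusters were not tested against each other. Of 30 tested HOX genes 7 fell and 0 rose, also adjusted over the list alone, and the 7 lie in the HOXA cluster (chromosome 7, 27092993 to 27200106). HOXA9 fell from 89.1 ± 7.54 to 36.6 ± 4.67 TPM (SD, n = 2), HOXA10 1.92-fold, HOXA5 2.36-fold and HOXA6 3.14-fold. The 10 tested HOXA genes had a median log2 fold change of -1.03 and the 20 of the other clusters a median of 0.05. The list was not shifted by camera (adjusted p = 0.29) and passed fry (adjusted p = 0.047). With the GC trend removed, camera at the preset correlation called it (adjusted p = 0.015). The 47 other tested genes within 5 Mb of the HOXA cluster had a median of -0.48, and 17 of them fell while 4 rose. The median of the HOXA genes minus that of these 47 genes was -0.54 (95% bootstrap interval -0.85 to 0.24, permutation p = 0.0087). By chromosome, the highest median log2 fold change was that of chromosome 22, at 0.22, or 0.13 with the GC trend removed. It was 0.19 in knockout 1 and 0.26 in knockout 2 against the controls, and 71 of its 388 tested genes rose while 10 fell. Genes around DEK at 6p22 were also lower. Of 15 tested 2 fell, TPMT 1.60-fold and SOX4 1.67-fold, also adjusted over the list alone, and the median was -0.33 (camera adjusted p = 0.0013, adjusted p = 0.38 with an estimated correlation).

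**Figure D4:**
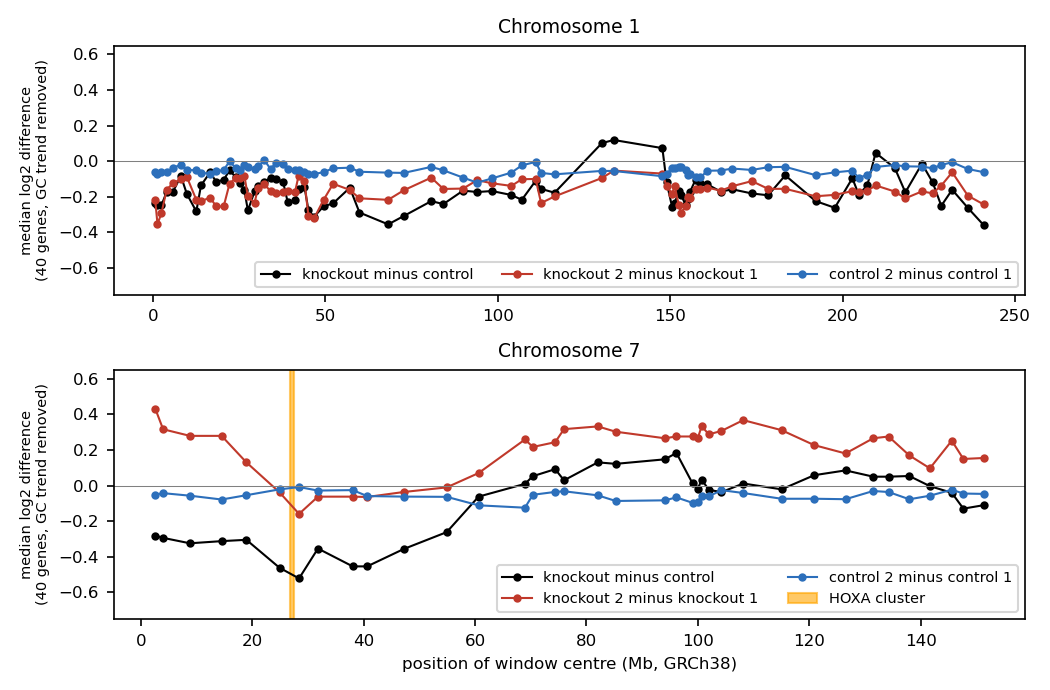
Median log2 difference of 40 neighbouring tested genes, with the GC trend removed, along chromosomes 1 and 7 (position in Mb, GRCh38), with black for knockout minus control, red for knockout 2 minus knockout 1 and blue for control 2 minus control 1. The red line lies below 0 along chromosome 1 and above 0 over most of chromosome 7, and the HOXA cluster is shaded.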

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

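The removal of the GC trend and the omission of chromosomes were chosen after the data were seen. The counts of changed genes rested on the spread between 2 libraries per group. Leaving out single libraries gave 47 to 5510 changed genes against 2804, and 47 to 1384 changed at least 2-fold against 949, with the lone sample of a group assumed to vary like the other group. DEK then had log2 fold changes of -2.37 to -1.41, and 17 to 18 lists were shifted. With no filter on low values 26 genes changed, all upwards and all by at least 2-fold, with 31270 genes tested, and DEK stayed at -1.89 but did not pass (adjusted p = 0.096). With no variance trend 1437 genes changed and DEK, again at -1.89, did not pass (adjusted p = 0.056). The cause was not tested for either setting. More genes fell than rose without knockout 1, without knockout 2 (1394 of 3092 rose), with the stricter filter (1337 of 2935), with the replicate block (1423 of 2971) and with the GC trend removed (1262 of 2790), and without knockout 1 this held at 2-fold or more as well (653 of 1384 rose). At an adjusted p under 0.01, 90 genes changed, 80 of them upwards. With an inter-gene correlation estimated per list, 0 lists passed, against 18, in a setting with so few degrees of freedom that a list could hardly pass. Among the named genes that passed and could be tested again, DEK aside, 88 of 107 lost their call without control 1 and 88 of 107 without control 2, 0 of 105 without knockout 1, 2 of 105 without knockout 2, 98 of 108 with no filter and 34 of 108 with no variance trend. Besides 2 settings that left out a library and the GC removal, the DNA repair list was lost with the stricter filter (adjusted p = 0.14), the median ratio (0.069), quantile normalization (0.13), no variance trend (0.066) and the omission of chromosomes (0.051), and the NRF2 list with the stricter filter (0.086) and no variance trend (0.078). None of the named genes or of the 18 lists reversed under any alternative run. Replicate numbers shared by the groups did not pair the samples, since nothing in the labels ties them to a day or culture, and the deviations of same-numbered libraries correlated at 0.099. With the replicate block 2971 genes changed, 1096 at least 2-fold, and 17 lists were shifted, with the NRF2 list lost (adjusted p = 0.053). The pseudocount, the stricter filter, both scalings, the GC removal and leaving out chromosomes kept the count of changed genes between 2476 and 2935.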

Other observations

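The tests of technical explanations in this part, and the gene groups outside the fixed lists, were chosen after the data were seen, while the lists and the limma fit were planned. Of 10 genes known as outputs of the ERK pathway, which share PHLDA1, SPRY2, SPRY4 and DUSP6 with the immediate early list and CCND1 with the HIF list, 8 rose and 0 fell. ETV4, an ETS factor, rose from 0.267 ± 0.069 to 9.81 ± 3.03 TPM (SD, n = 2), ETV5 from 7.83 ± 0.201 to 37.3 ± 4.55 TPM, DUSP4 from 1.19 to 5.79 TPM and DUSP6 from 1.83 to 10.6 TPM. EPHA2 and EPHA4 did not pass the test (limma adjusted p = 0.18 and 0.24), and EPHA4 was at 29.2 ± 0.388 and 18.1 ± 11.5 TPM. The group was not tested as a set. Of the 4 genes for HIF subunits and VHL, 0 rose and 1 fell in limma. EPAS1, encoding HIF-2 alpha, was at 67.1 ± 0.260 and 81.1 ± 4.77 TPM (adjusted p = 0.075), HIF1A at 12.6 and 13.4 TPM (adjusted p = 0.68), VHL at 28.7 and 33.1 TPM (adjusted p = 0.16), and ARNT fell from 32.4 to 20.9 TPM (adjusted p = 0.044).

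Of 8 tested genes of interferon signalling and nucleic acid sensing, 2 rose and 0 fell. STING1 rose from 42.3 ± 2.51 to 67.2 ± 8.38 TPM and IRF3 from 64.8 to 80.6 TPM (adjusted p = 0.030 and 0.047). CGAS was at 17.2 and 16.5 TPM (adjusted p = 0.72) and IFIH1 at 19.9 and 37.2 TPM (adjusted p = 0.13). IFNB1 was below 1 TPM in each library, at 0.118 and 0 TPM in the controls and 0.514 and 0.801 TPM in the knockouts, and was not tested.

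Chromosome blocks shifted together between the libraries: with the GC trend removed, the range of chromosome medians was 0.387 between the knockouts and 0.0225 between the controls, with chromosome 1 at -0.17 and chromosome 7 at 0.21 in knockout 2 against knockout 1. Around the HOXA cluster, 47 other genes within 5 Mb had a median of -0.48 (95% bootstrap interval -0.61 to -0.32), only just clear of a bound of -0.3 that was itself set after the fall was seen. These surroundings had first been drawn as the run of low windows (85 genes, median -0.52) and were redrawn at a fixed distance because that choice was circular. The median stayed at -0.38 (-0.52 to -0.19) with the GC trend removed, which argues against that trend as the whole cause, and a candidate explanation is a copy number difference between clones, for which no DNA data were used here. Whether the HOXA genes fell beyond their surroundings cannot be told apart from the regional shift: the difference of medians was -0.54 with a permutation p = 0.0087 (2-sided, over genes, which are not independent), but its bootstrap interval, -0.85 to 0.24, includes 0.

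The downward shift of 9 gene lists is small enough to raise the question of library bias. Over their 241 members the median was -0.26, against -0.06 over all tested genes, and it was -0.25 (95% bootstrap interval -0.27 to -0.20) with the GC trend removed (-0.06 over all genes), which argues against that trend as the whole cause except for the DNA repair list, whose median moved from -0.24 to -0.04. Since these lists were picked on both knockouts, a test against a shift of 1 knockout alone took the 7 or 8 lists that were lower in 1 knockout against 1 control and measured them in the other knockout against the other control, where, of 4 arrangements, the one whose interval came nearest to 0 gave a median, less that of all genes, of -0.17 (95% bootstrap interval -0.21 to -0.11). It replaced a test of the 9 lists in each knockout against shared controls, and it argues against such a shift for the lists it took. The intervals in this paragraph are from draws over genes, which are not independent, and leave out variation between libraries or clones. The 9 lists include that of genes near DEK (15 tested, median -0.33), which was drawn by position and to which proliferation need not apply. For the other lists, slower proliferation of the knockout cells, a clonal difference and an effect of DEK loss may each account for the downward shift. Proliferation was not measured here. The design cannot separate a clonal difference from an effect of DEK loss, because genotype and clone go together.

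Interferon-stimulated and antigen presentation genes were higher in the knockout, and 3 other sources were tested. With the GC trend removed the median over 42 members was 1.10 (95% bootstrap interval 0.83 to 1.33). Leukocytes were unlikely in cells derived by single-cell sorting, so this check had little room to find them. They would bring their own transcripts, but 2 of 16 leukocyte markers reached 1 TPM in both knockouts, against 1 in both controls. PTPRC stayed at or below 0.0129 TPM in the knockouts. A regional shift at 6p21 was argued against for the class I genes, since 123 neighbours within 2 Mb had a median of 0.0273 (-0.04 to 0.12) against 1.57 for the class I genes. A response to DEK loss may underlie the pattern, as may a stable difference between sorted clones or a reaction to the guide virus, which the control libraries are not stated to have received, and these stay open and untested.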
